A study of Arabidopsis thaliana with 45 samples.

How the data were processed

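Gene expression of imbibed seeds of the Arabidopsis thaliana line NILDOG1-Cvi was measured on 45 arrays, 24 of total RNA and 21 of polysomal RNA. The groups combine dormancy (dormant or non-dormant seeds), treatment (water or cordycepin), imbibition time (6 h or 24 h) and RNA type, which gives 16 groups, and each array was placed in its group from its title. The labels conflict in places. Their treatment protocol speaks of dry seeds at harvest where the titles and sample characteristics give imbibition times, and their molecule field names total RNA for every array where titles, characteristics and extraction protocol name polysomal RNA as well. The titles were followed, and what a group is rests on them. Per the labels, plants grew in randomized blocks and each replicate was a bulk of 8 plants, RNA was labelled with biotin, and how the non-dormant seeds were obtained is not given in the sources used here. The array type and the probe set definition are not given in the sources used here either. The p-values of single probe sets rest on a spread between replicates that was estimated over all 16 groups and both RNA types. They do not measure the spread between the bulks of the compared groups alone. Those of camera set the members of a list against the other probe sets.

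The deposited values are on a log2 scale and were made by the authors with RMA, a method that corrects background, normalizes the arrays to each other and summarises probes, per the submitters' processing notes, which name no version in the sources used here. The range of the values (0.418 to 12.75), the array medians (3.86 to 4.32) and the array means (4.57 to 4.67) fit such a scale. All columns matched a sample. The table holds 27827 probe sets named by locus, of which 27241 matched the locus tags of a reference table of assembly TAIR10.1 that was used for names only, and 10556 of these have a symbol. No further normalization was applied. Because RMA scales arrays to each other, a difference between polysomal and total RNA, or between times, is relative to the average transcript and not an absolute amount. The number of arrays limits the precision of each value.

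A linear model with 1 mean per group was fitted to all 45 arrays with limma 3.58.1 in R 4.3.3 (with data.table version 1.17.8), so that groups of 2 and 3 arrays shared 1 estimate of the spread (29 residual degrees of freedom, with a prior of 6.392 degrees of freedom and a prior SD of 0.294). Differences between group means were tested with moderated statistics. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and a difference of at least 2-fold is at least 1 on the log2 scale. The comparisons were non-dormant against dormant seeds for each treatment, time and RNA type, 24 h against 6 h, cordycepin against water, polysomal against total RNA, and the interactions of dormancy with RNA type, with time and with treatment. The comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to have been made later.

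Genes were named by a rule: in each comparison the 8 called genes with the largest rise and the 8 with the largest fall that have a symbol and whose compared groups do not overlap, up to 4 members of each list described, DOG1, and the members of the tryptophan and auxin biosynthesis list. The text gives part of the genes the rule yields. Of the lists, 21 were fixed by locus: tryptophan and auxin biosynthesis, auxin transport and response, indole glucosinolate and camalexin synthesis, dormancy regulators, ABA synthesis, ABA catabolism, ABA signalling, gibberellin synthesis, gibberellin inactivation and signalling, cell wall loosening, seed storage, late embryogenesis abundant genes, lipid mobilisation, cytosolic ribosomal proteins, ribosome biogenesis, cell cycle and DNA replication, heat shock, photosynthesis and chlorophyll, rapid stress response, seed coat markers and endosperm markers. With the 15 plastid-encoded and 92 mitochondrion-encoded probe sets this made 23 lists. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the 23 lists of a comparison, and again with an estimated correlation. Counts of called members are given over all probe sets and adjusted over the list alone.

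Overlaps between comparisons are set beside the number that independent lists of the same sizes would share, and comparisons set side by side this way had no array in common. Replicate numbers recur in every group, so it was checked whether arrays with the same number deviate together from their group means. In total RNA the correlation of same-numbered arrays had a median of 0.016 (-0.099 to 0.1), and in polysomal RNA 0.263 (-0.014 to 0.492), against -0.164 for arrays of different number. In total RNA the numbers were therefore not taken to pair the arrays. In polysomal RNA same-numbered arrays deviated together. The 3 pairs of 24 h with 6 h in non-dormant seeds in water correlated at 0.15 to 0.49. The 2 pairs of cordycepin with water in non-dormant seeds at 24 h correlated at 0.24 and 0.39. The main fit held no replicate block for any comparison and so leaves this shared deviation out of account. It stays in the error estimate, which the total RNA comparisons share. Fits with a block were run as alternatives. The closest arrays of all, replicates 2 and 3 of non-dormant seeds in cordycepin (total RNA, 24 h), differed by 0.392 (root mean square, log2), and no arrays were merged.

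The fit was tested on simulated data with the fitted means, spread and array numbers and no difference except in 200 of 27827 probe sets, 50 at each size. The simulated arrays varied independently, whereas real polysomal arrays of the same number deviated together, so the shares called with polysomal RNA are approximate. For non-dormant against dormant seeds in water, total RNA at 24 h, 52% of changes of 1 on the log2 scale and 100% of changes of 2 were called, with 3 false calls among 129. For the interaction of dormancy with RNA type at 24 h, 10% and 88% were called, with 2 false calls among 100. For cordycepin against water in polysomal RNA of dormant seeds at 24 h, 30% and 90% were called, with 9 false calls among 120. A simulated list of 16 members shifted by 1 was called by camera and 0 of 22 random lists were.

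The alternatives were a fit on only the compared arrays, the replicate number as a block, the lowest 25% of probe sets by mean value left out, a variance model with trend and robust estimation, quantile normalization over all arrays or within each RNA type, cyclic loess, array weights, each array left out in turn, and for lists an estimated correlation, the replicate block and fry. Chosen after seeing the data were a block within the polysomal arrays, leaving out the polysomal arrays numbered 2, a correction of the polysomal against total differences for their trend with mean value, and other error terms for the variance of the interaction with RNA type. The values carry no detection calls, so a level near or below an array's lower quartile (2.52 to 2.92 on total and 2.24 to 2.66 on polysomal RNA arrays) was read as open to background. Of 264 gene values named in the text, 47 have such a level in a compared group. Genome coordinates are not given, since the build behind the probe sets is not given in the sources used here.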

Results

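Seeds of an Arabidopsis thaliana near-isogenic line were profiled on 45 arrays to ask which transcripts, and which transcripts engaged in translation, differ between dormant and non-dormant seeds, and how far those differences depend on new transcription. The line, NILDOG1-Cvi in the labels, carries the DOG1 region of the accession Cvi in a Landsberg erecta background, and DOG1 (DELAY OF GERMINATION 1) is a major determinant of seed dormancy. Dormant and non-dormant seeds were imbibed for 6 h or 24 h in water or in cordycepin, an adenosine analogue that terminates RNA chains and is used to inhibit transcription. How far it did so in these seeds was not measured. Total RNA was measured on 24 arrays and polysomal RNA, the transcripts bound by several ribosomes, on 21 arrays. The 16 groups held 3 arrays each, except that polysomal RNA at 24 h had 2 arrays for dormant seeds in water, dormant seeds in cordycepin and non-dormant seeds in cordycepin. Each replicate was a bulk of 8 plants, per the labels. The values are log2 expression of 27827 probe sets, each named by a locus code, with array medians from 3.86 to 4.32, and the number of arrays limits their precision. On the first principal component, with 35.6% of the variance, the 24 h arrays of non-dormant seeds (71.8 to 119.3) lay apart from those of dormant seeds at 24 h (-5 to 28.5) and from all 6 h arrays (-62 to -27.9). The second component (25.2%) separated total from polysomal RNA, and the third (6.7%) separated dormant from non-dormant seeds at each time.

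**Figure D1:**
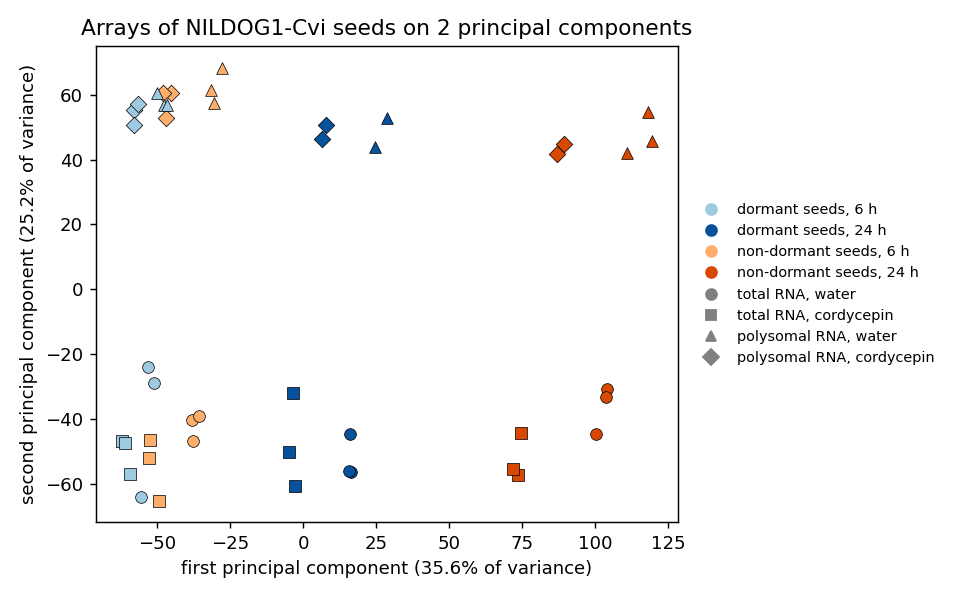
Scores of the 45 arrays on the first and second principal components of the log2 values of 27827 probe sets, 1 point per array; colour gives dormancy and imbibition time, and the marker gives RNA type and treatment. The axes carry 35.6% and 25.2% of the variance, and total RNA arrays (-65 to -23.9) and polysomal arrays (41.7 to 68.3) lie on opposite sides along the second.

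DOG1 (AT5G45830) itself was measured in every group. In total RNA at 6 h in water its level was 5.61 ± 0.32 in dormant and 5.28 ± 0.52 in non-dormant seeds (log2, mean ± SD, n = 3 each), a difference of -0.33 ± 0.27 (SE) that did not pass the limma test (adjusted p = 0.549). None of the 8 comparisons of non-dormant with dormant seeds called it, the nearest being total RNA at 6 h with cordycepin (-0.85 ± 0.27, adjusted p = 0.0563). DOG1 fell with imbibition in water: from 6 h to 24 h total RNA changed by -0.93 ± 0.27 in dormant and -1.18 ± 0.27 in non-dormant seeds (adjusted p = 0.011 and 0.000526). Polysomal RNA changed by -2.60 ± 0.30 and -2.01 ± 0.27 (adjusted p = 4.41e-08 and 1.04e-07). At 24 h DOG1 was lower in polysomal than in total RNA, with differences of -1.21 ± 0.30 in dormant seeds and -0.76 ± 0.27 in non-dormant seeds (adjusted p = 0.00458 and 0.049).

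After 6 h in water, NTL8 and EXPA10 were higher and LTI78 was lower in non-dormant than in dormant seeds. NTL8, a membrane-bound NAC transcription factor, stood at 9.51 ± 0.07 in non-dormant against 4.95 ± 0.53 in dormant seeds in total RNA (SD, n = 3 each), a log2 difference of 4.56 ± 0.25 (SE, adjusted p = 2.82e-15). The difference in polysomal RNA was 5.37 ± 0.25. The expansin gene EXPA10 rose by 3.83 ± 0.31 in total and 4.01 ± 0.31 in polysomal RNA, and the kinase gene MAPKKK19 by 3.49 ± 0.23 and 3.07 ± 0.23. The stress-responsive genes LTI78, AIRP2 and GolS2 (galactinol synthase) were lower in non-dormant seeds, with total RNA differences of -2.27 ± 0.23, -2.16 ± 0.17 and -2.01 ± 0.18. The seed heat shock factor HSFA9 was lower too (-2.01 ± 0.27). In all, 1651 probe sets passed in total RNA (865 higher and 786 lower in non-dormant seeds, of which 300 and 329 by at least 2-fold). Polysomal RNA gave 1249 (640 higher, 609 lower). Fitted on the compared arrays alone, total RNA gave 313 calls and polysomal RNA 443. Without replicate 2 or replicate 3 of the non-dormant total RNA group 1044 and 1091 were called, and without replicate 1 of the dormant polysomal group 832. Array weights gave 1919 in polysomal RNA, and a block within the polysomal arrays, chosen after seeing the data, 2667 in total and 2053 in polysomal RNA. Other normalizations turned the split of higher and lower calls, to 732 and 813 (quantile), 740 and 834 (quantile within RNA type) and 688 and 842 (cyclic loess) in total RNA. In polysomal RNA they gave 528 and 633, 555 and 665, and 554 and 718, so no direction is read from these splits.

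Among the gene lists fixed before the data were examined, gibberellin synthesis was shifted upwards at 6 h in both RNA types. In total RNA, 2 of its 10 members rose, GA20OX3 by 2.80 ± 0.25 and GA3OX1 by 1.23. In the same comparison 4 rose adjusted over the list alone (camera adjusted p = 0.0023, and adjusted p = 0.0209 with an estimated correlation). In polysomal RNA 3 members rose, 5 adjusted over the list alone, with GA3OX2 at 2.73 ± 0.47 from a dormant level of 2.62, which is open to background (camera adjusted p = 4.92e-05, and adjusted p = 0.00179 with an estimated correlation). Cell wall loosening genes were also shifted upwards, with 5 of 16 members higher in total RNA and 6 adjusted over the list alone, EXPA8 by 1.63 and EXPA1 by 1.32 besides EXPA10. The list's camera adjusted p was 0.000667, against adjusted p = 0.147 with an estimated correlation. Of the 8 late embryogenesis abundant (LEA) genes, which encode desiccation protectants, 3 fell in total RNA, also 3 adjusted over the list alone, led by RD29B at -1.14 (camera adjusted p = 0.000667, and adjusted p = 0.0989 with an estimated correlation). The abscisic acid (ABA) signalling list had 4 of 10 members higher, ABI4 (1.67), OST1 (1.61), ABI1 (1.21) and SNRK2.3 (0.66). This compares with 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.021, and adjusted p = 0.0989 with an estimated correlation). ABI1 is a phosphatase that represses ABA signalling, and the others promote it. In the list of 7 ABA synthesis genes, NCED5 (-1.33) and ABA1 (-0.71) fell, against 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.298). The tryptophan and auxin biosynthesis list showed no shift at 6 h. In it 1 of 25 members, TSA1, passed at -0.75, also 1 adjusted over the list alone (camera adjusted p = 0.784).

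After 24 h in water the serine carboxypeptidase-like gene scpl44 stood at 10.79 ± 0.06 in non-dormant and 3.42 ± 0.40 in dormant seeds in total RNA, a difference of 7.37 ± 0.34 (SE, n = 3 each, adjusted p = 2.04e-18). PYK10, a beta-glucosidase of endoplasmic reticulum bodies, was higher by 6.71 ± 0.33, the xyloglucan-modifying enzyme gene XTH31 by 5.79 ± 0.29, the pectin methylesterase gene PME3 by 5.58 ± 0.28 and the expansin gene EXPA2 by 4.96 ± 0.30. The dormant levels of PYK10 (2.66) and XTH31 (2.85) lay within the range of the arrays' lower quartiles (2.52 to 2.92), so the sizes of these differences are limited by background. In the other direction, the LEA gene ECP31 (-4.61 ± 0.20), the metallothionein gene AtMT4b (-4.21 ± 0.17), BGLU19 (-4.17 ± 0.22) and the galactinol synthase gene GolS1 (-3.68 ± 0.19) were lower in non-dormant seeds. In all, 5638 probe sets differed, 3215 higher and 2423 lower in non-dormant seeds, with 1707 and 992 by at least 2-fold.

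At 24 h cell wall and cell cycle lists rose, and storage, LEA and heat shock lists fell. Of 16 cell wall loosening genes 13 rose, the same number adjusted over the list alone (camera adjusted p = 1.01e-19). Of 18 cell cycle and DNA replication genes 13 rose, 15 adjusted over the list alone (2.42e-11), among them PCNA1 (3.34), MCM2 (4.92-fold higher) and MCM3 (2.27). All 12 seed storage genes fell, with OLEO2, an oil body oleosin, at -2.44 and CRU2, a cruciferin, at -2.06 (camera adjusted p = 5.04e-22). So did all 8 LEA genes (camera adjusted p = 3.02e-15), and both counts were the same adjusted over the list alone. Of 14 heat shock genes 10 fell, also 10 adjusted over the list alone, led by HSFA9 (-3.51), HSP23.6 (-3.49) and HSP101 (-3.34), with a camera adjusted p of 1.06e-15. With an estimated correlation these 5 lists stayed called, at adjusted p = 0.000117, 7.27e-07, 0.000431, 0.000117 and 0.000117. Photosynthesis and chlorophyll genes had 4 of 22 members higher, RBCS1A by 2.27, also 4 adjusted over the list alone (camera adjusted p = 0.158). Cytosolic ribosomal protein genes had 4 of 23 higher, 4 adjusted over the list alone, with RPS21B at 1.12 (camera adjusted p = 0.00324, and adjusted p = 0.288 with an estimated correlation). Ribosome biogenesis had 2 of 12 higher, BRX1-1 (0.72) and NOP58-2 (0.51), lipid mobilisation 3 of 17 higher with CSY2 at 2.37-fold, and the rapid stress response 2 higher and 3 lower of 18 with ZAT10 at -1.97. These counts were the same adjusted over the list alone, and none of those 3 lists was called by camera (adjusted p = 0.117, 0.065 and 0.288).

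Lists of endosperm and seed coat markers were tested beside these groups, and whether the seeds differed in tissue composition was not tested. Of 9 endosperm markers EXPA2 was higher and EPR1 lower (-1.31), also 1 and 1 adjusted over the list alone, with no shift of the list (camera adjusted p = 0.894). None of the 7 seed coat markers was called by limma in total RNA, and 0 adjusted over the list alone (camera adjusted p = 0.799). Mitochondrion-encoded transcripts were lower in non-dormant seeds for 18 of 92 probe sets, 18 adjusted over the list alone, with a median of -0.35 (camera adjusted p = 4.9e-06, and adjusted p = 0.288 with an estimated correlation). None of the 15 plastid-encoded probe sets was called in that comparison, and 0 adjusted over the list alone (camera adjusted p = 0.501).

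Tryptophan and indole metabolism, the pathway named in the study's title, differed at 24 h. Of the 25 genes of tryptophan and auxin biosynthesis, 9 were higher and 4 lower in non-dormant seeds, against 10 and 4 adjusted over the list alone (camera adjusted p = 0.013, and adjusted p = 0.0342 with an estimated correlation). CYP79B2 and CYP79B3, which turn tryptophan into indole-3-acetaldoxime, rose by 2.75 ± 0.24 and 2.31 ± 0.31 (adjusted p = 3.47e-11 and 3.12e-07). ASA1, an anthranilate synthase subunit, rose by 1.59 ± 0.20, TAR2 by 1.34, TSA1 by 1.28, PAT1 by 1.05, TAA1 by 1.04, IGPS by 0.94 and TSB1 by 0.46. The members that fell were AAO1, an aldehyde oxidase (-2.06 ± 0.16), the flavin monooxygenase genes YUC8 (-0.99) and YUC2 (-0.62), and TSB2 (-0.54). MYB34 in dormant and YUC8 in non-dormant seeds (2.61) stood at levels open to background. Of 14 genes of indole glucosinolate and camalexin synthesis, 6 rose, also 6 adjusted over the list alone. They were led by CYP83B1 at 4.69 ± 0.22, the regulator MYB34 at 3.31 ± 0.36 (dormant level 2.81), CYP81F2 at 2.42 and SUR1 at 2.26 (camera adjusted p = 1.38e-05, and adjusted p = 0.00148 with an estimated correlation). Genes of auxin transport and response went both ways, 4 higher (PIN3 by 2.03) and 3 lower (IAA2 at -1.61) of 18. The counts were 5 and 3 adjusted over the list alone, with no shift (camera adjusted p = 0.849).

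Hormone genes tied to dormancy went different ways at 24 h. Gibberellin synthesis had 5 of 10 members higher, 5 adjusted over the list alone, led by GA3OX1 (2.78), GA3OX2 (2.29) and GA20OX3 (2.05), with a camera adjusted p of 0.000556 (adjusted p = 0.00176 with an estimated correlation). In the 11 genes of gibberellin inactivation and signalling, the receptor genes GID1A (-1.48) and GID1C (-0.71) fell and RGL2 (0.59), a repressor, rose. Of them 1 was higher and 2 lower adjusted over the list alone (camera adjusted p = 0.277). ABA synthesis had NCED5 (-2.32) and ABA1 (-1.77) lower and NCED6 (1.04, from a dormant level of 2.28 that is open to background) higher of 7, the same adjusted over the list alone (camera adjusted p = 0.0367, and adjusted p = 0.0704 with an estimated correlation). ABA catabolism had 1 of 3 lower, CYP707A2 at -0.54, and 2 adjusted over the list alone (camera adjusted p = 0.216). ABA signalling had ABI5 (-1.17), HAI1 (-1.06) and HAB1 (-1.05) lower and ABI4 (0.95) higher of 10. There were 4 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.998). Of 10 dormancy regulators 5 fell, led by MFT (-2.74) and the phosphatase gene AHG1 (-1.10), and SPT rose by 1.79. The counts were the same adjusted over the list alone (camera adjusted p = 0.00755, and adjusted p = 0.0342 with an estimated correlation).

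In polysomal RNA at 24 h, from 3 arrays of non-dormant and 2 of dormant seeds, scpl44 (7.06 ± 0.38, SE) and XTH31 (5.80 ± 0.33) were higher and HSP23.6 (-4.49 ± 0.21) and BGLU19 (-4.24 ± 0.25) lower in non-dormant seeds. CYP79B2 (2.80), CYP79B3 (2.62), CYP83B1 (3.91), MYB34 (3.43), GA3OX2 (4.42) and GA3OX1 (9.82-fold) were higher. All 12 seed storage and all 8 LEA genes were lower, and 12 and 8 adjusted over the list alone. Photosynthesis genes had 10 of 22 members higher, 10 adjusted over the list alone, with PORC at 1.99 (camera adjusted p = 0.000694, and adjusted p = 0.00664 with an estimated correlation). Of 5135 probe sets called, 2872 were higher and 2263 lower. Across genes, which are not independent replicates, the total and polysomal differences correlated at 0.84 at 24 h (Spearman 0.70) and 0.52 at 6 h (Spearman 0.41). At 24 h, 3878 probe sets were called the same way in both RNA types, 2216 higher and 1662 lower. Independent lists would share 332 and 197, and 1 was called in opposite directions. Without replicate 2 of the dormant polysomal group, which leaves 1 dormant array, 3343 polysomal calls were made, and with only the compared arrays fitted 3286.

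**Figure D2:**
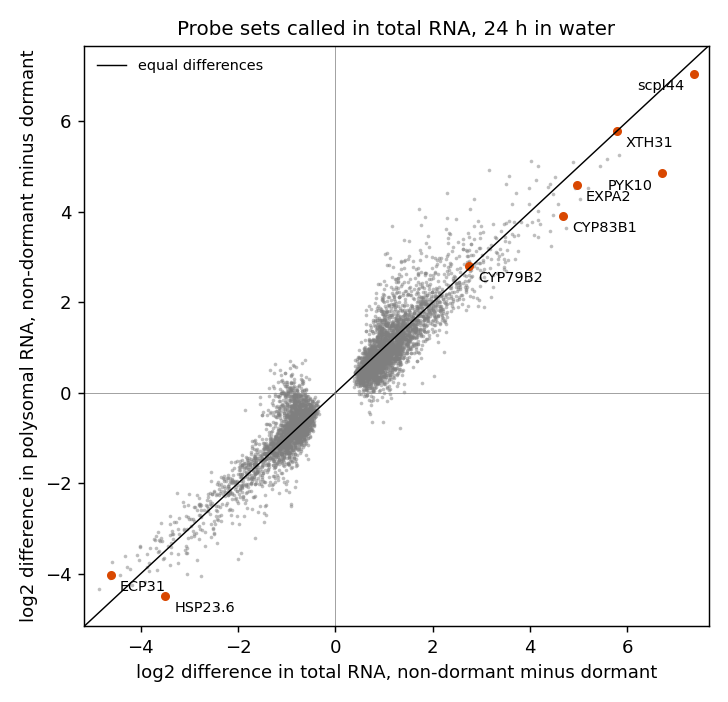
Log2 difference of non-dormant from dormant seeds after 24 h in water, total RNA on the horizontal and polysomal RNA on the vertical axis, for the 5638 probe sets called in total RNA, with the line of equality; orange points are named genes. Of the plotted probe sets 3878 were called the same way in polysomal RNA, and the correlation over all 27827 probe sets is 0.84.

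The interaction of dormancy with RNA type tested whether the dormancy difference in polysomal RNA departed from that in total RNA. At 24 h it called 2 probe sets, FLA2 (a fasciclin-like arabinogalactan protein gene) at 2.52 ± 0.46 (SE, adjusted p = 0.0458) and AT5G09820 at 1.71 ± 0.31 (adjusted p = 0.0458). At 6 h it called AT5G35120 at 2.44 ± 0.42 (adjusted p = 0.0426). The loci without a symbol were named after their values were seen. AT5G35120 stood at 1.75 in polysomal RNA of dormant seeds and at 1.78 and 2.73 in total RNA of non-dormant and dormant seeds, and AT5G09820 at 2.48 in polysomal RNA of dormant seeds, levels that are open to background. Photosynthesis genes as a list were shifted upwards at 24 h (median 0.23, camera adjusted p = 0.00464, and adjusted p = 0.0444 with an estimated correlation), with no member called and 1 higher adjusted over the list alone. Plastid-encoded transcripts were shifted down at 6 h (median -0.42, camera adjusted p = 4.5e-06, and adjusted p = 0.036 with an estimated correlation). So were mitochondrion-encoded ones (median -0.26, camera adjusted p = 1.36e-06, and adjusted p = 0.616 with an estimated correlation), with no member of either called and 0 adjusted over the list alone. At an unadjusted p under 0.05 limma gave 1120 probe sets at 24 h and 1486 at 6 h. At 24 h 0 passed with only the compared arrays fitted, with quantile normalization over all arrays or with the replicate block over all arrays (FLA2 and AT5G09820 both at adjusted p = 0.0529), and with trend and robust estimation FLA2 alone passed. The block within the polysomal arrays gave 5, and without the polysomal arrays numbered 2, which leaves 1 dormant polysomal array, there were 2, with 0 of the calls named here. At 6 h 0 passed with only the compared arrays, after cyclic loess, or without the lowest 25% of probe sets by mean value, a filter that removes AT5G35120. Without the polysomal arrays numbered 2 there were 3. At 24 h none passed without any 1 array of the total RNA groups or without replicate 1 of either polysomal group, and 1 without replicate 3 of the non-dormant polysomal group. At 6 h none passed without any 1 dormant polysomal array, without replicate 1 of the non-dormant polysomal group or without replicate 1 or 2 of either total RNA group. There 2 passed without replicate 3 of the non-dormant polysomal group.

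The interaction of dormancy with time asked, in total RNA, which dormancy differences changed between 6 h and 24 h. Among genes with a symbol, PYK10 (7.37 ± 0.46, SE), scpl44 (6.15 ± 0.49) and XTH31 (6.12 ± 0.41) rose in that difference. Their levels were low in the other groups: PYK10 stood at 2.88 and 2.66 in dormant seeds at 6 h and 24 h and 2.22 in non-dormant seeds at 6 h, XTH31 at 3.19, 2.85 and 2.86, and scpl44 at 3.24 and 3.42 in dormant seeds. The lower quartile of the total RNA arrays ran from 2.52 to 2.92, so the sizes of these interactions, and their order, are limited by background. HSP23.6 (-3.95 ± 0.27), ECP31 (-3.94 ± 0.29) and AtMT4b (-3.80 ± 0.24) fell. CYP83B1 (5.05 ± 0.32), CYP79B2 (3.28 ± 0.35) and ASA1 (2.03 ± 0.28) were called with positive interactions. All 12 seed storage genes had negative ones, 12 adjusted over the list alone (camera adjusted p = 2.32e-22, and adjusted p = 0.000489 with an estimated correlation). In all, 2595 probe sets were called, 1395 with a more positive difference at 24 h and 1200 with a more negative one. Of the 1651 and 5638 probe sets called in total RNA at 6 h and 24 h, 386 were higher and 414 lower at both times, against 99.9 and 68.4 for independent lists, and 66 went opposite ways.

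Dormant and non-dormant seeds were also compared with cordycepin present. How far cordycepin blocked transcription was not measured, so a difference that stayed is not read as independent of new transcription. In polysomal RNA of non-dormant seeds in water, 3197 probe sets rose at least 2-fold from 6 h to 24 h. Of these, 367 were called lower with cordycepin and 7 higher in total RNA at 24 h. At 6 h NTL8 was higher in non-dormant seeds by 3.43 ± 0.25 (SE) in total RNA, EXPA10 by 2.79 ± 0.31 and MAPKKK19 8-fold. LTI78 was lower (-2.24 ± 0.23). In polysomal RNA at 6 h NTL8 was higher by 4.04 ± 0.25 and LTI78 lower (-2.43 ± 0.23). At 24 h GASA6, a gibberellin-regulated gene, was higher by 6.53 ± 0.30, EXPA2 by 5.51 ± 0.30, NCED6 by 3.78 and GA20OX3 by 2.98 in total RNA. ECP31 (-3.76 ± 0.20) and HSFA9 (-3.72 ± 0.27) were lower. The dormant levels of GASA6 (2.18), EXPA2 (2.48) and NCED6 (2.27) lay under the lower quartile of every total RNA array and that of MYB34 (2.70) within the range of these quartiles, so the sizes of these 4 differences are limited by background. CYP79B2 (0.02 ± 0.24, adjusted p = 0.978) and CYP79B3 (-0.09 ± 0.31, adjusted p = 0.914) were not called with cordycepin, whereas CYP83B1 (3.20 ± 0.22) and MYB34 (2.24 ± 0.36) were. The tryptophan and auxin list had 2 members higher and 3 lower of 25, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.687). The indole glucosinolate list had 6 of 14 higher, 6 adjusted over the list alone (camera adjusted p = 3.22e-05, and adjusted p = 0.00227 with an estimated correlation). In polysomal RNA at 24 h NAC044 (4.79 ± 0.48), EXPA2 (4.75 ± 0.37), NCED6 (4.21 ± 0.44) and GA3OX2 (4.16 ± 0.58) were higher and HSP101 (-3.48 ± 0.18) was lower, from 2 arrays a group.

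With cordycepin, NTL8 and EXPA2 were among 1343 total RNA calls at 6 h (681 higher and 662 lower in non-dormant seeds) and 4633 at 24 h (2465 and 2168). Polysomal RNA gave 824 (382 and 442) and 3773 (2142 and 1631). Across genes the water and cordycepin dormancy differences correlated at 0.78 in total RNA at 24 h, with 3475 probe sets called the same way in both and 2 in opposite ways. Independent lists would share 285 higher and 189 lower. Fitted on the compared arrays alone, the 6 h counts were 221 in total and 160 in polysomal RNA and the 24 h polysomal count was 1753. Without replicate 1 of the dormant total RNA group at 6 h 790 were called, without replicates 1, 2 and 3 of the non-dormant one in turn 803, 884 and 756. In polysomal RNA the counts were 532 without replicate 1 of the dormant and 521 and 542 without replicates 1 and 3 of the non-dormant group. Array weights gave 1653 in polysomal RNA at 6 h, the block within the polysomal arrays 2237 in total and 1414 in polysomal RNA at 6 h, and the fit without the polysomal arrays numbered 2 gave 2060 in polysomal RNA at 24 h, from 1 array a group. Other normalizations turned the 6 h total RNA split, to 609 higher and 653 lower (quantile), 601 and 651 (quantile within RNA type) and 555 and 636 (cyclic loess).

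The interaction of dormancy with treatment, in total RNA at 24 h, asked which dormancy differences cordycepin altered. PBP1, a jacalin-related lectin that binds PYK10, was called lower (-3.52 ± 0.32, SE, adjusted p = 1.11e-08), as were KCS8 (-2.75 ± 0.46) and CYP79B2 (-2.73 ± 0.35, adjusted p = 2.45e-05). XTH31 (-2.70 ± 0.41), CYP79B3 (-2.39 ± 0.44) and CYP83B1 (-1.49 ± 0.32) were also called. NCED6, which makes the ABA precursor xanthoxin, was called higher (2.74 ± 0.50, adjusted p = 0.00532), as were ABCB4 (2.01 ± 0.27) and CRF6 (2.01 ± 0.42). Dormant seeds in water and cordycepin had levels of 2.28 and 2.27 for NCED6, 2.01 and 1.61 for PBP1 and 1.41 and 1.74 for KCS8, and non-dormant seeds in cordycepin 2.56 for PBP1 and 2.54 for KCS8. XTH31 stood at 2.85 in dormant seeds in water. These levels are open to background, so the sizes of these interactions and their order are limited by it. As a list, tryptophan and auxin biosynthesis was shifted down (median -0.27), with 2 of 25 members called lower, 8 adjusted over the list alone (camera adjusted p = 7.27e-07, and adjusted p = 0.000396 with an estimated correlation). Seed storage genes were shifted up (median 0.48) with no member called, 8 adjusted over the list alone (camera adjusted p = 8.39e-09, and adjusted p = 0.0416 with an estimated correlation). In all, 82 probe sets were called, 25 with a more positive dormancy difference in cordycepin and 57 with a more negative one. Without replicate 1 or 2 of the non-dormant water group 45 and 54 were called, without replicate 3 of the non-dormant cordycepin group 46, and with only the compared arrays fitted 48. Array weights gave 263 (101 and 162), and the block within the polysomal arrays 133 (51 and 82).

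**Figure D3:**
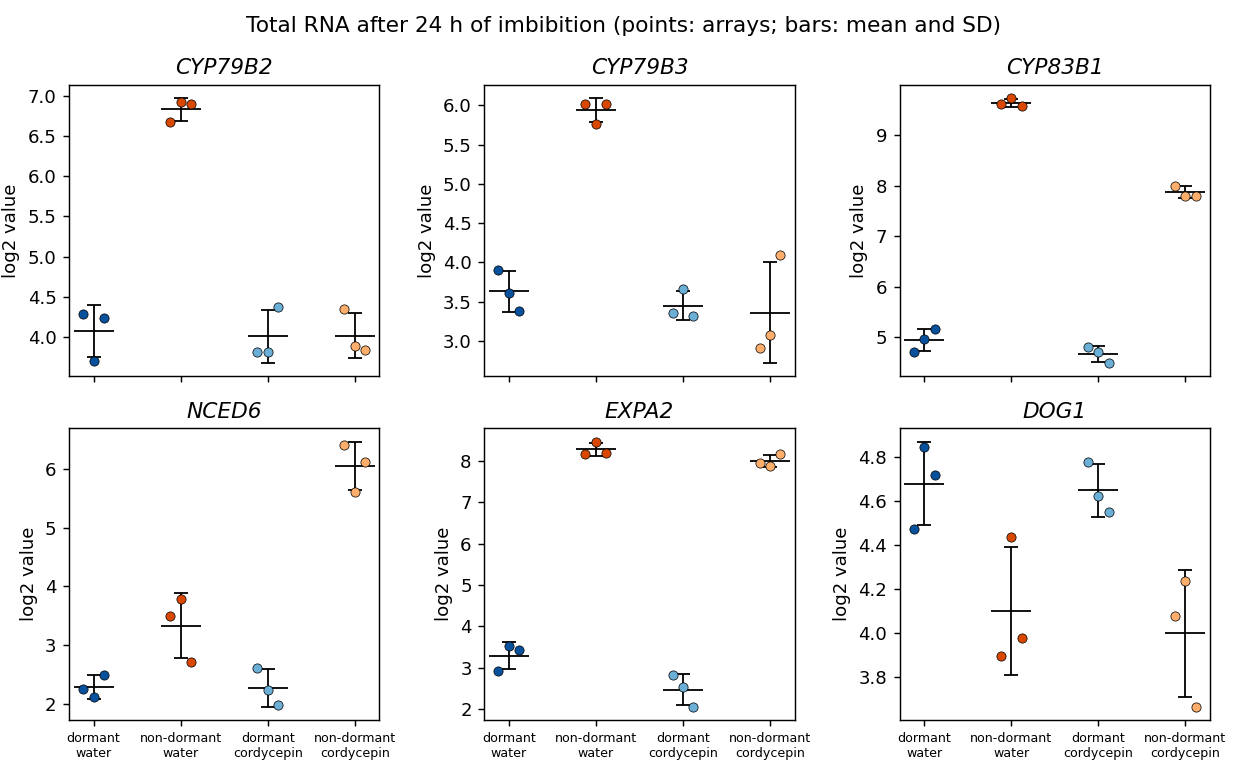
Log2 values of CYP79B2, CYP79B3, CYP83B1, NCED6, EXPA2 and DOG1 on the total RNA arrays at 24 h, 1 panel per gene; points are arrays and bars mark group means of 3 arrays with SD. CYP79B2 averaged 6.83 in non-dormant seeds in water against 4.02 in cordycepin, and 4.08 and 4.01 in dormant seeds.

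Cordycepin was then set against water within each kind of seed. In non-dormant seeds at 24 h, PBP1 was lower with cordycepin in total RNA (-3.93 ± 0.22, SE, n = 3 each, adjusted p = 1.26e-14), as were FAR1 (-3.15 ± 0.33), CYP79B2 (-2.80 ± 0.24), CYP79B3 (-2.58 ± 0.31), PYK10 (-2.54 ± 0.33) and the glucosinolate sulfotransferase gene SOT17 (-2.53 ± 0.33). NCED6 (2.73 ± 0.36), the cytokinin response factor gene CRF6 (2.72 ± 0.30), NAC044 (2.63 ± 0.39) and the transporter gene ABCB4 (2.49 ± 0.19) were higher. PBP1 in cordycepin (2.56) and NCED9 in water (2.86) stood at levels open to background. Of the 25 tryptophan and auxin genes 8 fell, ASA1 (-0.90), TSA1 (-0.82), TSB1 (-0.82), IGPS (-0.70), PAT1 (-0.69) and NIT3 (-0.67) besides CYP79B2 and CYP79B3, and YUC2 rose (0.89). There were 12 lower and 1 higher adjusted over the list alone (camera adjusted p = 6.96e-09, and adjusted p = 1.99e-05 with an estimated correlation). In the indole glucosinolate list 4 of 14 fell, led by CYP83B1 (-1.77) and SUR1 (-1.65), with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000416, and adjusted p = 0.0106 with an estimated correlation). ABA synthesis had 3 of 7 higher, NCED6, NCED5 (1.66) and NCED9 (1.35), and 4 adjusted over the list alone (camera adjusted p = 1.14e-08, and adjusted p = 1.99e-05 with an estimated correlation). Seed storage had 9 of 12 higher, 11 adjusted over the list alone, with SESA4 at 0.95 (camera adjusted p = 3.08e-13, and adjusted p = 0.00878 with an estimated correlation). The cell cycle list had 5 of 18 lower, 10 adjusted over the list alone, with CYCD1;1 at -1.54 (camera adjusted p = 2.65e-09, and adjusted p = 3.58e-06 with an estimated correlation). In all, 912 probe sets were called, 429 higher and 483 lower with cordycepin. Without replicate 1 of the water group 553 probe sets were called, and without replicate 1 or 3 of the cordycepin group 591 and 577. Array weights gave 2089 (1005 higher, 1084 lower), and the block within the polysomal arrays 1395 (697 and 698).

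In polysomal RNA of non-dormant seeds at 24 h, PBP1 (-3.77 ± 0.25, SE), CYP79B2 (-2.60 ± 0.27) and CYP79B3 (-2.36 ± 0.34) were lower with cordycepin, and NAC044 (3.15 ± 0.44), CRF6 (2.89 ± 0.33) and NCED6 (2.73 ± 0.40) higher. The 751 calls (402 higher, 349 lower) came from 2 cordycepin and 3 water arrays. Of the probe sets called in total and polysomal RNA, 234 were higher and 194 lower in both, against 6.2 and 6.06 for independent lists, and 0 were called in opposite directions. Without replicate 1 or 2 of the cordycepin group 489 and 318 were called, with only the compared arrays fitted 188, and without the polysomal arrays numbered 2, which leaves 1 cordycepin array, there were 379. Cyclic loess turned the split to 370 higher and 373 lower.

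In dormant seeds at 24 h the stachyose synthase gene STS was higher with cordycepin in total RNA by 1.93 ± 0.28 (SE, adjusted p = 9.47e-05), and GASA6 (-1.88 ± 0.30), EXPA1 (-1.62 ± 0.25) and GH3.5 (-1.44) were lower. The auxin transport and response list was shifted down there, GH3.5 being called and 3 of 18 adjusted over the list alone (camera adjusted p = 0.000946, and adjusted p = 0.0101 with an estimated correlation). In polysomal RNA the phenylalanine ammonia-lyase gene PAL1 was lower (-2.39 ± 0.38, adjusted p = 0.00127) and the alternative oxidase gene AOX1A higher (1.93 ± 0.37). GASA6 (2.18) and PAL1 (1.86) with cordycepin and AOX1A (1.98) in water stood at levels open to background. Plastid-encoded transcripts were shifted down on polysomes, 2 of 15 called and 9 adjusted over the list alone (median -0.54, camera adjusted p = 1.04e-14, and adjusted p = 0.000114 with an estimated correlation). In all, 321 probe sets were called in total RNA (194 higher, 127 lower) and 105 in polysomal RNA (43 higher, 62 lower). Fitted on the compared arrays alone, limma called 1 in total RNA and 0 in polysomal RNA, where 2267 probe sets had an unadjusted p under 0.05 in the fit over all arrays. In total RNA 169 and 151 were called without replicate 1 or 3 of the cordycepin group and 170 and 157 without replicate 2 or 3 of the water group. In polysomal RNA the counts were 160 and 58 without replicate 1 or 2 of the cordycepin group and 4 without replicate 2 of the water group. Array weights gave 682 in total and 43 in polysomal RNA, the block within the polysomal arrays 661 and 301, and the fit without the polysomal arrays numbered 2 gave 14 in polysomal RNA. That fit compares 1 array with 1, each assumed to vary like the other groups.

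At 6 h GA20OX3 was lower with cordycepin in non-dormant seeds in total (-1.19 ± 0.25, SE, adjusted p = 0.0308) and polysomal RNA (-1.50 ± 0.25, adjusted p = 0.0101) and in dormant seeds in polysomal RNA (-1.39 ± 0.25, adjusted p = 0.0304). In non-dormant seeds total RNA of EXPA8 (-1.79 ± 0.24), NTL8 (-1.23 ± 0.25) and the ABA receptor gene PYL4 (-1.15 ± 0.18) was also lower, and in dormant seeds total RNA of SDH3-1 (-3.01 ± 0.51) was lower and that of BGLU22 (2.01 ± 0.42) higher. The other probe sets called in polysomal RNA of dormant seeds, AT3G32280 (2.45) and AT1G28660 (-1.97), were named after their values were seen. The lower group of each stood at a level open to background, SDH3-1 at 1.35 and AT1G28660 at 1.03 with cordycepin, and BGLU22 at 2.24 and AT3G32280 at 1.27 in water, so the sizes of these 4 differences are limited by it. Ribosome biogenesis genes were shifted down in non-dormant seeds, with no member called, in total RNA (median -0.20, 4 of 12 adjusted over the list alone, camera adjusted p = 7.34e-05, and adjusted p = 0.0411 with an estimated correlation). They were also shifted down in polysomal RNA, with no member called (median -0.27, 3 adjusted over the list alone, camera adjusted p = 7.88e-07, and adjusted p = 0.00662 with an estimated correlation). Total RNA gave 56 calls in dormant seeds (29 higher, 27 lower) and 23 in non-dormant seeds (6 higher, 17 lower), and polysomal RNA 3 (1 higher, 2 lower) and 7 (1 higher, 6 lower).

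The 6 h cordycepin counts moved up and down with the setting and with single arrays. With only the compared arrays fitted limma called 0 in each of these 4 comparisons, against 2925 and 2351 in total RNA and 1272 and 1937 in polysomal RNA of dormant and non-dormant seeds at an unadjusted p under 0.05 in the fit over all arrays. Array weights gave 13 and 101 calls in total and 19 and 119 in polysomal RNA of dormant and non-dormant seeds, and the block within the polysomal arrays 157 and 99, and 8 and 64. The replicate block over all arrays gave 39 in non-dormant total RNA and 1 and 17 in polysomal RNA of dormant and non-dormant seeds, and without the lowest 25% of probe sets these were 42, 1 and 15. Trend and robust estimation gave 52 in total and 14 in polysomal RNA of non-dormant seeds. In dormant total RNA quantile normalization over all arrays gave 118 (56 higher, 62 lower, a turned split) and within RNA type 106. Without the polysomal arrays numbered 2 limma called 0 in polysomal RNA of either kind of seed. In non-dormant total RNA cyclic loess gave 24 calls (10 higher, 14 lower) and quantile normalization within each RNA type 29 (11 and 18). In dormant polysomal RNA quantile normalization over all arrays gave 5 (3 and 2), cyclic loess 2 (1 and 1) and quantile within RNA type 2 (1 and 1). In dormant total RNA 27 were called without replicate 1 of the cordycepin group, as without replicate 2 of the water group. In non-dormant total RNA 10 and 14 were called without replicate 1 or 2 of the cordycepin group and 9, 8 and 8 without replicates 1, 2 and 3 of the water group. In dormant polysomal RNA 0 were called without replicate 1 or 2 of the cordycepin group, and 1, 0 and 0 without replicates 1, 2 and 3 of the water group. In non-dormant polysomal RNA 3, 2 and 0 were called without replicates 1, 2 and 3 of the cordycepin group and 0 without replicate 1 or 2 of the water group.

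Imbibition from 6 h to 24 h in water was compared within each kind of seed. In dormant seeds the cell wall genes CWLP (3.91 ± 0.28, SE) and XYL1 (3.64 ± 0.30) and the mannanase gene MAN7 (2.97 ± 0.23) rose in total RNA. The dark-inducible DIN2 (-3.59 ± 0.24) and the cold-regulated RCI2A (-3.43 ± 0.26) and LTI30 (-3.42 ± 0.33) fell. In non-dormant seeds PYK10 rose by 7.15 ± 0.33 and GASA6 by 6.93 ± 0.30, and DIN2 (-5.59 ± 0.24), LTI30 (-5.51 ± 0.33) and GolS1 (-4.61 ± 0.19) fell. The 6 h levels of PYK10 (2.22) and GASA6 (2.15) lay below the lower quartile of every total RNA array, so the sizes of these rises are limited by background. Cytosolic ribosomal protein genes rose in both kinds of seed, 22 of 23 in total RNA in each, 22 adjusted over the list alone, with RPS21B at 1.88 in dormant and 2.77 in non-dormant seeds (camera adjusted p = 6.47e-28 and 2.11e-16, and adjusted p = 0.00069 and 0.00304 with an estimated correlation). Cell cycle genes rose too, 10 of 18 in dormant seeds with 1 lower and 15 in non-dormant seeds, the same adjusted over the list alone, MCM2 by 1.40 and 3.61 (camera adjusted p = 0.000112 and 3.87e-12, and adjusted p = 0.00069 and 3.56e-07 with an estimated correlation). CYP79B2 fell in dormant seeds (-0.82) and rose in non-dormant seeds (2.46). All 12 seed storage genes fell in non-dormant seeds, 12 adjusted over the list alone, and in dormant seeds 2 fell, SESA4 (-1.54) and SESA1 (-0.65), and 4 adjusted over the list alone. The interaction of dormancy with time tested these differences. In polysomal RNA AGP31 (3.81 ± 0.29) and GRP4 (3.40 ± 0.26) were higher at 24 h in dormant seeds, and GASA6 (7.03 ± 0.30, from a 6 h level of 2.53 open to background) was higher and HSP23.6 (-4.93 ± 0.19) lower in non-dormant seeds.

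Non-dormant seeds, with PYK10 and GASA6, had 8826 calls with time in total RNA (4638 higher and 4188 lower at 24 h) and 9747 in polysomal RNA (4946 and 4801), and dormant seeds 5041 (2674 and 2367) and 3992 (2209 and 1783). Between dormant and non-dormant seeds 3583 probe sets were called the same way in total RNA, 2035 higher and 1548 lower. This compares with 446 and 356 for independent lists, and 84 opposite ways. The dormant counts were 2793 in total and 2248 in polysomal RNA with only the compared arrays fitted, and 2571 in polysomal RNA without replicate 2 of the dormant 24 h group. Other normalizations turned the dormant total RNA split, to 2416 higher and 2439 lower (quantile), 2443 and 2465 (quantile within RNA type) and 2368 and 2529 (cyclic loess). Quantile normalization turned the non-dormant polysomal split, to 4635 and 4807 over all arrays and 4656 and 4896 within RNA type.

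Polysomal and total RNA of the same kind of seed were compared in water to see which transcripts were over- or under-represented on polysomes. Scaling makes each such difference relative to the average transcript. Transcripts of the extensin genes EXT10 and EXT6 and the MADS-box genes AGL51 and AGL78 were lower in polysomal RNA in all 4 comparisons. EXT10 had differences of -4.72 ± 0.29 and -5.75 ± 0.32 (SE) in dormant seeds at 6 h and 24 h and -5.68 ± 0.29 and -5.07 ± 0.29 in non-dormant seeds. In polysomal RNA EXT10 stood at 2.24, 1.59, 1.70 and 1.62 in these 4 groups, EXT6 at 1.42, 1.09, 1.19 and 1.21, AGL51 at 2.16, 2.01, 2.61 and 1.80 and AGL78 at 3.25, 3.46, 2.68 and 2.59. The lower quartile of the polysomal arrays ran from 2.24 to 2.66, so the sizes of these differences, and their order between groups, are limited by background. Organelle-encoded transcripts were lower as well. Of 92 mitochondrion-encoded probe sets 58 and 54 fell in dormant seeds at 6 h and 24 h and 69 and 64 in non-dormant seeds. The counts were 60, 66, 75 and 72 adjusted over the list alone (medians -0.92, -0.85, -1.15 and -0.85; camera adjusted p from 9.91e-53 to 5.21e-38, and adjusted p at most 0.0111 with an estimated correlation). Of 15 plastid-encoded probe sets 9, 5, 12 and 7 fell, and 10, 5, 13 and 10 adjusted over the list alone, with adjusted p at most 0.0111 with an estimated correlation. Higher in polysomal RNA were SK13 (2.03 ± 0.33) and AOX1A (1.96 ± 0.30) in dormant seeds at 6 h, IAA30 (1.90 ± 0.55) in dormant seeds at 24 h, and TXND9 (1.93 ± 0.28) and MT1B (2.14 ± 0.47) in non-dormant seeds at 6 h and 24 h. The total RNA levels of SK13 (2.76), AOX1A (2.24) and MT1B (1.47) there are open to background. The gibberellin receptor gene GID1C was higher in all 4 (1.11, 1.12, 1.11 and 0.54).

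EXT10 was among 6772 and 4607 probe sets called in dormant seeds at 6 h and 24 h and 6926 and 4123 in non-dormant seeds. In dormant seeds at 6 h 3573 were higher and 3199 lower, and cyclic loess turned this to 2304 higher and 2670 lower. In non-dormant seeds at 6 h the split was 3686 and 3240, turned by cyclic loess to 2556 and 3029. The calls of at least 2-fold were mostly lower, 1932 against 770 in dormant seeds at 6 h, 1903 against 597 in dormant seeds at 24 h, and 2039 against 672 and 1357 against 335 in non-dormant seeds. Between dormant and non-dormant seeds the polysomal against total differences correlated across genes at 0.82 at 6 h and 0.80 at 24 h, with 4375 and 2449 probe sets called the same way. Independent lists would share 473 higher and 372 lower, and 146 and 197. Without replicate 3 of the dormant total RNA group at 6 h 3977 were called. At 24 h the counts were 2187 without replicate 2 of the dormant polysomal group, 2608 without its replicate 1, 2231 without replicate 2 of the non-dormant total group and 2713 without replicate 3 of the non-dormant polysomal group. With only the compared arrays fitted the dormant counts were 2891 and 2591. Without the polysomal arrays numbered 2 the dormant count at 24 h was 2631, from 1 polysomal array, and correction for the trend with mean level, an alternative chosen after seeing the data, gave 461 higher calls of at least 2-fold in dormant seeds at 6 h in place of 770.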

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

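The comparisons of variances for the interaction with RNA type, and the naming of 2 loci without a symbol, were chosen only after the result was seen.

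Results were taken up here where a test of the difference between groups passed. The dormancy difference changed with time in total RNA for 2595 probe sets, among them PYK10 (7.37), scpl44 (6.15), XTH31 (6.12), CYP83B1 (5.05), CYP79B2 (3.28) and ASA1 (2.03), and in the other direction HSP23.6 (-3.95), ECP31 (-3.94) and AtMT4b (-3.80), with a median of -1.55 for the seed storage list. Cordycepin changed it at 24 h for 82 probe sets, among them PBP1 (-3.52), KCS8 (-2.75), CYP79B2 (-2.73), XTH31 (-2.70), CYP79B3 (-2.39), CYP83B1 (-1.49), NCED6 (2.74), ABCB4 (2.01) and CRF6 (2.01). The sizes for PYK10, XTH31, PBP1, KCS8 and NCED6 are limited by background in 1 or more of the groups behind them. The list medians for cordycepin were -0.27 for tryptophan and auxin biosynthesis and 0.48 for seed storage. The interaction with RNA type called 2 probe sets at 24 h, FLA2 (2.52) and AT5G09820 (1.71), and 1 at 6 h, AT5G35120 (2.44). Their limma adjusted p ran from 0.0426 to 0.0458. AT5G09820 and AT5G35120 stood at levels open to background in some of the groups, and at each time none passed under some of the other settings. The list medians of that interaction were 0.23 for photosynthesis and chlorophyll at 24 h and -0.42 and -0.26 for plastid-encoded and mitochondrion-encoded transcripts at 6 h. The mitochondrion-encoded list was not called with an estimated correlation (adjusted p = 0.616).

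In non-dormant seeds at 24 h, the tryptophan and auxin biosynthesis and the indole glucosinolate lists were shifted down with cordycepin. For CYP79B2 and CYP79B3 a difference in range left by normalization is argued against. They moved by at most 0.236 under quantile or cyclic loess normalization over all arrays and stayed called. This test did not cover the smaller differences of other members. A loss of newly made transcripts alone was predicted to leave transcripts that decline with time near 0. That holds only if their decline needs no new transcripts, which was not tested. The 2288 probe sets that fell at least 2-fold from 6 h to 24 h on the polysomal arrays had a median cordycepin difference of 0.25 in total RNA (quartiles 0.01 and 0.48). The median was 0.01 over all 27827, and of those that fell 274 were called higher and 11 lower. The 3197 that rose had a median of -0.33 (quartiles -0.64 and -0.10), with 367 called lower and 7 higher, and the arrays that sorted the probe sets were not those that gave the cordycepin differences. Seeds less far along the 6 h to 24 h change would show both medians, a hypothesis made after the gene list directions were known. A loss of new transcripts on which the falls depend would show them too, so the medians do not separate these explanations. An effect on this pathway alone was not tested.

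Few probe sets passed the interaction of dormancy with RNA type. In simulated data at the same array numbers 24% of 2-fold interactions were called at 6 h and 10% at 24 h. The simulated arrays varied independently, unlike polysomal arrays of the same number, so these shares are approximate. For single genes a lack of 2-fold interactions cannot be told apart from too few arrays. Over all probe sets, the variance of the interaction beyond its error at 24 h was -0.03 times that of the total RNA dormancy difference, and 0.0901 times at 6 h. The negative value means that the error estimate exceeded the variance of the interaction at 24 h (0.171 against 0.16), for a reason that was not tested. With a block within the polysomal arrays the ratios at 24 h and 6 h were 0.0227 and 0.235. With the replicate block over all arrays they were -0.0157 and 0.164. The covariance between differences made from arrays of different replicate number, which needs no error estimate, gave 0.178 at 6 h (0.0178 to 0.248 over 3 pairs of numbers) and 0.0688 at 24 h, from 1 pair and so with no range. This is consistent with dormancy differences that were mostly alike in both RNA types, as a hypothesis, with a single pair behind the last value at 24 h and ratios up to 0.248 at 6 h.

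Other splits of the same arrays were tried for each comparison of groups with at least 3 arrays. With 10 splits a share under 0.05 cannot be reached. Every other split mixed the compared arrays within groups, so a real difference between them enters the error and can lower the count. Except where said, the real split was the 1 split with a count as large. For non-dormant against dormant seeds the real counts and the highest of the other splits were 1651 and 8 (total, 6 h), 5638 and 1 (total, 24 h) and 1249 and 1 (polysomal, 6 h) in water, and 1343 and 5, 4633 and 0, and 824 and 1 with cordycepin. For time they were 5041 and 7 and 8826 and 0 in total RNA of dormant and non-dormant seeds, and 9747 and 0 in polysomal RNA of non-dormant seeds. For cordycepin against water they were 321 and 0 and 912 and 0 in total RNA at 24 h of dormant and non-dormant seeds, and at 6 h 23 and 1 in total RNA of non-dormant seeds, 3 and 2 in polysomal RNA of dormant seeds and 7 and 0 in that of non-dormant seeds. For polysomal against total RNA they were 6772 and 3 (dormant, 6 h), 6926 and 0 (non-dormant, 6 h) and 4123 and 4 (non-dormant, 24 h). For cordycepin against water in total RNA of dormant seeds at 6 h, 3 of the 10 splits called as many, with 56 in the real split and 89 in the highest other.

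For the interactions 100 of 200 splits were drawn, and chance cannot be excluded by the counts over all of these splits. With the real split included, 19 gave as many calls as the interaction with RNA type at 6 h (real 1, highest other 3247), 6 as many as that with time (real 2595, highest other 5423) and 12 as many as that with treatment (real 82, highest other 7748). Counts several times the real one point to a structure of the samples. Of the other splits with as many calls, 16, 5 and 11 mixed dormant and non-dormant arrays unequally in the 2 arms, which carries part of the dormancy difference into the interaction. The 48 other splits that mixed them alike called at most 1, 2 and 1 probe sets, against 1, 2595 and 82 in the real splits. Among the splits mixed alike, no other came near the real counts for time and treatment. For RNA type at 6 h another reached the real count.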

How the results depend on the processing

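The block within polysomal arrays, the fit without the polysomal arrays numbered 2 and the trend correction were chosen only after the result was seen. Counts are calls, limited in precision by array number. Where a count moved by more than 1.5 times the cause was not tested, but fewer arrays give fewer degrees of freedom. The polysomal block moves total RNA counts only through the error estimate. With each array left out in turn the ranges for non-dormant against dormant seeds were, in water, 1044 to 1499 (total, 6 h), 4488 to 4864 (total, 24 h), 832 to 1005 (polysomal, 6 h) and 3343 to 4796 (polysomal, 24 h). With cordycepin they were 756 to 1279, 3707 to 3975, 521 to 652 and 2632 to 2964. Where this, or leaving out the polysomal arrays numbered 2, left 1 array in a group, that array was assumed to vary like the others. For the interactions they were 0 to 2 (RNA type, 6 h), 0 to 3 (RNA type, 24 h), 2096 to 2559 (time) and 45 to 88 (treatment). For cordycepin against water in total RNA they were 27 to 83 and 151 to 233 (dormant, 6 h and 24 h) and 8 to 21 and 553 to 658 (non-dormant). In polysomal RNA they were 0 to 3, 4 to 160, 0 to 5 and 318 to 777. For time they were 4003 to 4533 and 7695 to 8021 in total RNA of dormant and non-dormant seeds, and 2571 to 3623 and 8590 to 9257 in polysomal RNA. For polysomal against total RNA they were 3977 to 6566 and 2187 to 3921 (dormant, 6 h and 24 h) and 5048 to 5723 and 2231 to 3176 (non-dormant). With only the compared arrays, 20 of 28 counts moved. The dormancy counts in water went to 313 (total, 6 h), 443 (polysomal, 6 h) and 3286 (polysomal, 24 h), and with cordycepin to 221, 160 and 1753. The interactions with RNA type went to 0 (limma), that with treatment to 48, and time in dormant seeds to 2793 (total) and 2248 (polysomal). The cordycepin counts went to 1 in total RNA of dormant seeds at 24 h, 188 in polysomal RNA of non-dormant seeds at 24 h. They went to 0 by limma in the 4 comparisons at 6 h and in polysomal RNA of dormant seeds at 24 h, where the fit over all arrays gave 2925, 2351, 1272, 1937 and 2267 at an unadjusted p under 0.05. Polysomal against total RNA in dormant seeds went to 2891 and 2591. Array weights moved 10 counts. The dormancy counts in polysomal RNA at 6 h went to 1919 in water and 1653 with cordycepin, and the treatment interaction to 263. The cordycepin counts went in total RNA to 13 and 682 (dormant, 6 h and 24 h) and 101 and 2089 (non-dormant), and in polysomal RNA to 19 and 43 (dormant) and 119 (non-dormant, 6 h). The replicate block over all arrays moved 4, the RNA type interaction at 24 h to 0, and cordycepin at 6 h to 39 (total, non-dormant), 1 (polysomal, dormant) and 17 (polysomal, non-dormant). That block gave 10151 against 9747 for time in polysomal RNA of non-dormant seeds. The block within polysomal arrays moved 13. The dormancy counts at 6 h went to 2667 (total) and 2053 (polysomal) in water and 2237 and 1414 with cordycepin, the interactions with RNA type at 24 h to 5 and with treatment to 133. The cordycepin counts went in total RNA to 157 and 661 (dormant) and 99 and 1395 (non-dormant), and in polysomal RNA to 8 and 301 (dormant) and 64 (non-dormant, 6 h). Without the polysomal arrays numbered 2, dormancy with cordycepin moved to 2060 (polysomal, 24 h), the RNA type interaction at 6 h to 3, cordycepin in polysomal RNA to 0 and 14 (dormant, 6 h and 24 h) and 0 and 379 (non-dormant). Polysomal against total RNA in dormant seeds at 24 h went to 2631. Without the lowest 25% of probe sets by mean value, the RNA type interaction at 6 h moved to 0 and cordycepin at 6 h to 42 (total, non-dormant), 1 (polysomal, dormant) and 15 (polysomal, non-dormant). With trend and robust estimation the RNA type interaction at 24 h moved to 1, and cordycepin at 6 h in non-dormant seeds to 52 (total) and 14 (polysomal). Quantile normalization over all arrays moved the RNA type interaction at 24 h to 0 and cordycepin at 6 h in dormant seeds to 118 (total) and 5 (polysomal), quantile normalization within RNA type the former of these to 106, and cyclic loess the RNA type interaction at 6 h to 0. At an unadjusted p under 0.05 limma gave the RNA type interactions 1486 (6 h) and 1120 (24 h). The trend correction took higher calls of at least 2-fold (dormant, 6 h) from 770 to 461, and their overlap was not counted. Of the named genes, 2 changed sign, both near 0 and not called in the dormancy comparison with cordycepin in total RNA at 24 h. CYP79B2 (0.02) went to -0.03 with either quantile normalization, -0.10 with cyclic loess and -0.06 with array weights, and ranged from -0.14 to 0.21 with each array left out. CYP79B3 (-0.09) ranged from -0.45 to 0.14 with each array left out. Of the 264 values named for genes, 47 were no longer called with only the compared arrays, 17 with quantile normalization over all arrays, 7 with cyclic loess, 4 with trend and robust estimation, 4 with the replicate block and 2 with array weights. With quantile normalization within RNA type it was 9 of 234, without the lowest 25% of probe sets 1 of 259 and without the polysomal arrays numbered 2 it was 16 of 89. Over all single arrays left out it was 198 of 1657 refitted values. The correlation of total and polysomal dormancy differences went from 0.52 to 0.61 at 6 h and from 0.84 to 0.88 at 24 h without the lowest 25% of probe sets. Of the called lists 111 of 227 were lost with an estimated correlation, 25 with fry and 2 with the replicate block.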

Other observations

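Both tests of the larger number of falls in polysomal RNA were chosen only after the result was seen, and the one on organelle transcripts replaced another.

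On polysomes at 6 h in water, the LEA and ABA synthesis lists were shifted down and the cell wall loosening list up in non-dormant seeds. Of 8 LEA genes 3 fell, RD29B by 1.41 ± 0.20 (log2, SE), ECP31 by 0.71 and LEA4-5 by 0.61. There were 7 adjusted over the list alone (camera adjusted p = 1.75e-07, and adjusted p = 0.0113 with an estimated correlation). NCED5 (-1.21) and ABA1 (-0.81) were the called members of 7 in the ABA synthesis list, against 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00611, and adjusted p = 0.0285 with an estimated correlation). Of 16 cell wall loosening genes 5 rose, 6 adjusted over the list alone, among them EXPA8 (1.98), EXPA9 (1.85) and EXPA3 (1.74), with a camera adjusted p of 1.87e-06 (adjusted p = 0.0285 with an estimated correlation). Ribosome biogenesis had 1 of 12 higher, PES at 0.41. The count was 5 adjusted over the list alone (camera adjusted p = 9.32e-05, and adjusted p = 0.0285 with an estimated correlation). Plastid-encoded transcripts were lower for 4 of 15, 7 adjusted over the list alone (median -0.32, camera adjusted p = 1.87e-06, and adjusted p = 0.0113 with an estimated correlation). At 24 h cell cycle genes rose on polysomes in 14 of 18 cases, 15 adjusted over the list alone, with PCNA1 at 2.85 and CYCD1;1 at 2.32 from a dormant level of 2.59 that is open to background (camera adjusted p = 5.01e-13, and adjusted p = 1.67e-07 with an estimated correlation). Tryptophan and auxin genes had 7 higher, with TSA1 at 1.36 and PAT1 at 1.30, and 2 lower of 25. They were 10 and 3 adjusted over the list alone (camera adjusted p = 0.00383, and adjusted p = 0.0131 with an estimated correlation).

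On polysomes of non-dormant seeds at 24 h, the rapid stress response and seed storage lists were shifted upwards with cordycepin. The zinc finger genes ZAT12 (1.79 ± 0.28, SE) and ZAT10 (1.40 ± 0.26) were the called members of 18 in the rapid stress response list, 3 adjusted over the list alone (camera adjusted p = 0.00028, and adjusted p = 0.0242 with an estimated correlation). Seed storage had 7 of 12 higher, 10 adjusted over the list alone, with CRU2 at 1.20 (camera adjusted p = 3.78e-15, and adjusted p = 0.00456 with an estimated correlation). Of 18 cell cycle genes CYCD1;1 (-1.22) and CYCA2;3 (-1.17) were called lower, 9 adjusted over the list alone (camera adjusted p = 5.58e-08, and adjusted p = 1.48e-05 with an estimated correlation). Of 22 photosynthesis genes PORC was 4.3-fold lower, and 2 were lower adjusted over the list alone (median -0.39, camera adjusted p = 0.00028, and adjusted p = 0.00527 with an estimated correlation). With time in water, 13 of 14 heat shock genes fell in total RNA of non-dormant seeds, 13 adjusted over the list alone (camera adjusted p = 8.25e-16, and adjusted p = 0.000223 with an estimated correlation). ZAT12 (-2.02 in dormant and -2.96 in non-dormant seeds) and ZAT10 (-1.77 and -2.88) fell with time as well. In the comparison of non-dormant with dormant seeds in cordycepin at 6 h, total RNA of HSP17.6B (1.61), HSFA2 (0.95) and HSP90.1 (0.60) was higher and that of HSFA9 (-1.75) lower. This compares with 6 and 1 of 14 adjusted over the list alone (camera adjusted p = 0.0366, and adjusted p = 0.406 with an estimated correlation).

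In each comparison of polysomal with total RNA, calls of at least 2-fold were more often lower than higher, with ratios of 2.51 and 3.19 in dormant seeds at 6 h and 24 h and 3.03 and 4.05 in non-dormant seeds. A difference in range between the RNA types is argued against as the whole cause, since correction for the trend with mean level left ratios of 3.44 to 4.73. Organelle transcripts are argued against as the whole cause too, since the ratios were 2.44 to 3.92 without them. The test that this one replaced found mitochondrial medians of at most -0.93 after the trend correction. Loss of transcripts in the polysome preparation and lower ribosome loading stay open and were not tested.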
